A study of Arabidopsis thaliana with 9 samples.

How the data were processed

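FIE occupancy was measured by ChIP-seq in 9 libraries of Arabidopsis thaliana (strain Ws, 30 hr old plants): 3 replicates each of anti-FIE chromatin from the wild type, anti-FIE chromatin from plants with RNA interference transgenes against BPC and ZnF genes, and wild-type input. Libraries were made with a ThruPLEX kit, per the labels' protocols. The submitters' processing notes name Bowtie2, bedtools, MACS2 2.1.0.20151222 and the TAIR10 genome build, without saying which step each served. The authors deposited 1 peak list per anti-FIE group in the narrowPeak layout. How the 3 replicates and the input entered each list is not given in the sources used here. One list names the wild type. The other carries an abbreviation that the labels do not spell out and was taken as the BPC and ZnF knockdown, since that was the one remaining anti-FIE group.

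Each deposited row gives an interval, a score, a fold enrichment ratio at the summit, a −log10 p-value, a −log10 q-value and the summit offset. The deposited score equalled 10 times the −log10 q cut to a whole number in 100% of rows. Every deposited −log10 q was above 10, and the peak numbers had gaps (highest 35125 in the wild type and 40491 in the knockdown), so the deposited lists held at most 18.6% and 12.1% of the numbered calls. A site below this filter is absent from a list even if it was enriched, so a missing peak is not a measured absence of FIE. Fold values were compared within a list and not between lists, since they depend on the depth and the filter.

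Depth per library is not given in the peak lists. A relative depth was recovered from the deposited fold and −log10 p, which together fix a whole-number summit pileup and a background under the Poisson model of the caller, with a pseudocount of 1 in the fold. The largest misfit was 7.27e-04 on the −log10 p scale. The lowest background was 16.9 in the wild type and 7.95 in the knockdown. At 874 pairs of summits within 30 bp of each other the knockdown background was a median of 0.471 times that of the wild type (interquartile range 0.467 to 0.475). This median equals the ratio of the lowest values. The match is not an independent check of depth, since 27.05% of wild-type and 58.17% of knockdown summits had a background at about the lowest value. A wild-type peak was expected to pass at the knockdown depth when its pileup and background, scaled by this ratio, gave a −log10 p of at least 12.4, the lowest in the knockdown list. The expected number of passing peaks was the sum of binomial probabilities over the thinned pileups. This relies on the recovered background following depth, with the same fragment length in both lists. It also takes occupancy as equal in both groups. Among weak peaks of the gene-poor regions it gave fewer passing peaks than were shared.

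A peak was shared when it overlapped a peak of the other list by at least 1 bp. Chance overlap came from 1000 random placements of the other list on the same chromosomes (one-sided). For shares on the arms or in the gene-poor regions alone, each placed peak stayed inside or outside the gene-poor region, as it was. Shares have 95% Wilson intervals, which cover the sampling of peaks alone. Medians were compared by two-sided permutation tests with 100000 resamples (10000 under the alternatives), and counts by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over lists, families, location classes or chromosomes. Gene-poor regions were, on each chromosome, the longest run of 100 kb bins whose protein-coding gene number, smoothed over 5 bins, was under 0.5 times the median bin. They covered 16.9 Mb, and the rest, including any shorter gene-poor runs, was called arms. This split and the depth filter were chosen after the data were seen.

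Gene positions came from a RefSeq gene table of the TAIR10.1 assembly, used to place peaks relative to genes. Printed coordinates are those of the peak lists on TAIR10. No coordinate was converted, and the nuclear chromosome sequences of both assembly names were taken to be the same. As a check, peaks were shifted along the chromosomes. Of the arm summits found only in the wild type, 58.4% lay in protein-coding genes without a shift, and 47.2% to 50.8% did at shifts of 500 to 2000 bp, although shifts of 5000 bp gave 57.5% and 58.2%. The table gives no strand or exons, so exon, intron and UTR classes were not used. Pseudogenes are the genes that this table types as such, and transposable element genes were not told apart within that class. A gene was bound when a peak overlapped its body by at least 1 bp, in place of the planned rule of the body plus 1 kb upstream. Shares and tests of genes were not adjusted for gene length. Motif tests were not run, since no genome sequence was used here.

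The 14 gene lists (144 genes) were fixed before the data were examined, as were the tests and the rule for named items. Of these genes, 139 were matched by symbol or synonym and 5 by locus code. The rule named the members of each list with the highest wild-type fold, the 10 strongest peaks found only in the wild type, the 5 strongest found only in the knockdown and the 5 strongest shared peaks. Other genes named individually were chosen after their values were seen. Families were matched by words in the gene descriptions. Families with fewer than 10 genes (growth-regulating factor, defensin and transposable element genes) were left out.

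The alternatives were 50% reciprocal overlap, the summit inside a peak of the other list, peaks within 500 bp, the upper part of each list by q, equal list sizes, fold quintiles, other gene rules, the arms and gene-poor regions apart, the depth filter, a stricter gene-poor limit and placement within regions. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. The functions were tested on simulated data. Pileup and background were recovered in 100% of 2000 simulated peaks, overlap calls equalled a plain double loop in 100% of 1200 cases, and 100% of 1636 planted shared peaks were found. Permutation tests called 5% of 100 simulated comparisons without a difference and 96% of 50 with a planted shift. List tests called 1% of 200 simulated lists without enrichment and 99% of 200 with it.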

Results

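FIE is a core subunit of Polycomb repressive complex 2 (PRC2), the complex that places the repressive H3K27me3 mark on histone H3. Its occupancy was profiled by chromatin immunoprecipitation and sequencing in Arabidopsis thaliana plants of the Ws strain at the age of 30 hr. The series held 9 libraries in 3 groups of 3 replicates: anti-FIE chromatin from the wild type, anti-FIE chromatin from plants with RNA interference transgenes against BPC and ZnF genes (the double knockdown), and wild-type input chromatin. BPC proteins are plant GAGA-motif binding factors. The labels do not spell out ZnF, which is read here as zinc finger, and do not say which genes the transgenes target. The comparison asked where FIE was bound in the wild type and which of these sites kept a FIE peak in the double knockdown. The files gave 1 peak list per group of anti-FIE libraries, so the replicates could not be compared with each other. All tests below therefore run over peaks or genes of these lists, and their p-values and intervals do not cover the variation between plants. Expression of the targeted genes was not measured by these data.

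The wild-type list held 6540 peaks over 2.79 Mb of the nuclear chromosomes, with a median length of 252.5 bp and a median fold enrichment at the summit of 3.29 (interquartile range 3.03 to 3.89). The knockdown list held 4882 peaks over 1.36 Mb, with a median length of 147 bp. Fold enrichment is the authors' value from the peak caller and is used here within its own list. The background recovered from the peak values was 16.9 in the wild-type list and 7.95 in the knockdown list, a ratio of 2.12, and was taken as their difference in depth. The smallest summit pileup was 53 in the wild-type list and 35 in the knockdown list. A weak wild-type peak could therefore be missed in the knockdown list at equal occupancy. For this reason, values are also given for the 1624 wild-type peaks that would still pass at the knockdown depth.

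Few wild-type FIE peaks on the chromosome arms had a counterpart in the knockdown list, whereas most of those in the gene-poor regions did. On the arms, 248 of 4900 wild-type peaks overlapped a knockdown peak (5.06%, 95% Wilson interval 4.48 to 5.71), and 4652 did not. In the gene-poor regions, 1215 of 1640 wild-type peaks did (74.1%, 71.9 to 76.2). The odds ratio between the regions was 53.6, with a −log10 p of 677.3 by a one-sided Fisher's exact test. Over the whole genome 1463 wild-type peaks were shared (22.4%, 21.4 to 23.4) and 5077 were found only in the wild type. Random placement of the knockdown peaks over whole chromosomes gave a mean of 2.83% over the genome. Placement that kept each knockdown peak on the arms or in the gene-poor region gave 3.70% over the genome. It gave 1.45% on the arms and 10.3% in the gene-poor regions. The one-sided permutation p was 0.001 in each case, the smallest that 1000 placements can give.

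The same contrast between regions was seen for peaks strong enough to pass at the knockdown depth. Of 976 such wild-type peaks on the arms, 84 overlapped a knockdown peak (8.61%, 7.01 to 10.5) and 892 did not. Of 648 such peaks in the gene-poor regions, 597 did (92.1%, 89.8 to 94.0). Thinning the pileup of every wild-type arm peak to the knockdown depth gave 1189 peaks expected to pass, against the 248 that were shared. In the gene-poor regions the order was the other way, with 711.6 expected to pass and 1215 shared. There the strong peaks were close to the expectation (606.9 expected, 597 shared), but of the 992 weaker ones 104.7 were expected and 618 were shared. Thinning takes occupancy as equal in both groups. A failure of the depth model for these weak peaks therefore cannot be told apart from a stronger knockdown signal there. Of the other 3924 arm peaks, which were not expected to pass singly, 320.1 were expected by thinning, 164 were shared and 3760 had no knockdown peak. In base pairs, 3.74% of the wild-type peak length on the arms and 77.2% of that in the gene-poor regions was also covered by knockdown peaks.

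**Figure D1:**
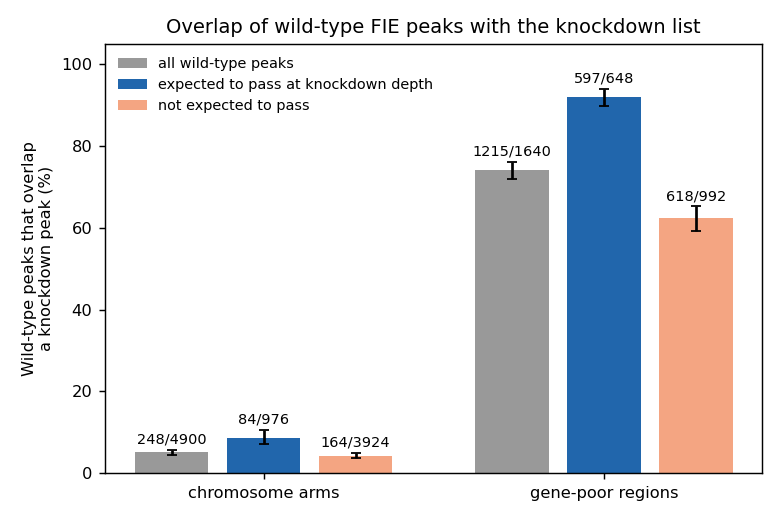
Share of wild-type FIE peaks (percent, y axis) that overlap a knockdown peak by at least 1 bp, on the chromosome arms and in the gene-poor regions, for all peaks, for peaks expected to pass at the knockdown depth and for the others. Error bars are 95% Wilson intervals over peaks and the counts stand above the bars; among peaks expected to pass, 84 of 976 arm peaks and 597 of 648 gene-poor peaks were shared.

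Read from the knockdown list, 1352 of its 4882 peaks overlapped a wild-type peak (27.7%, 26.5 to 29.0), against 3.79% by random placement (permutation p = 0.001, the smallest possible). The share was 10.5% on the arms and 43.7% in the gene-poor regions, where 1423 of 2529 knockdown peaks had no wild-type counterpart. The series held no input of the knockdown plants, so peaks found only in the knockdown lack a control from the same plants. The knockdown list lay more in the gene-poor regions than the wild-type list did, with 2529 peaks (51.8%) against 1640 (25.1%), an odds ratio of 3.21 and a −log10 p of 189.1 by a one-sided Fisher's exact test. These regions made up 14.2% of the genome.

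**Figure D2:**
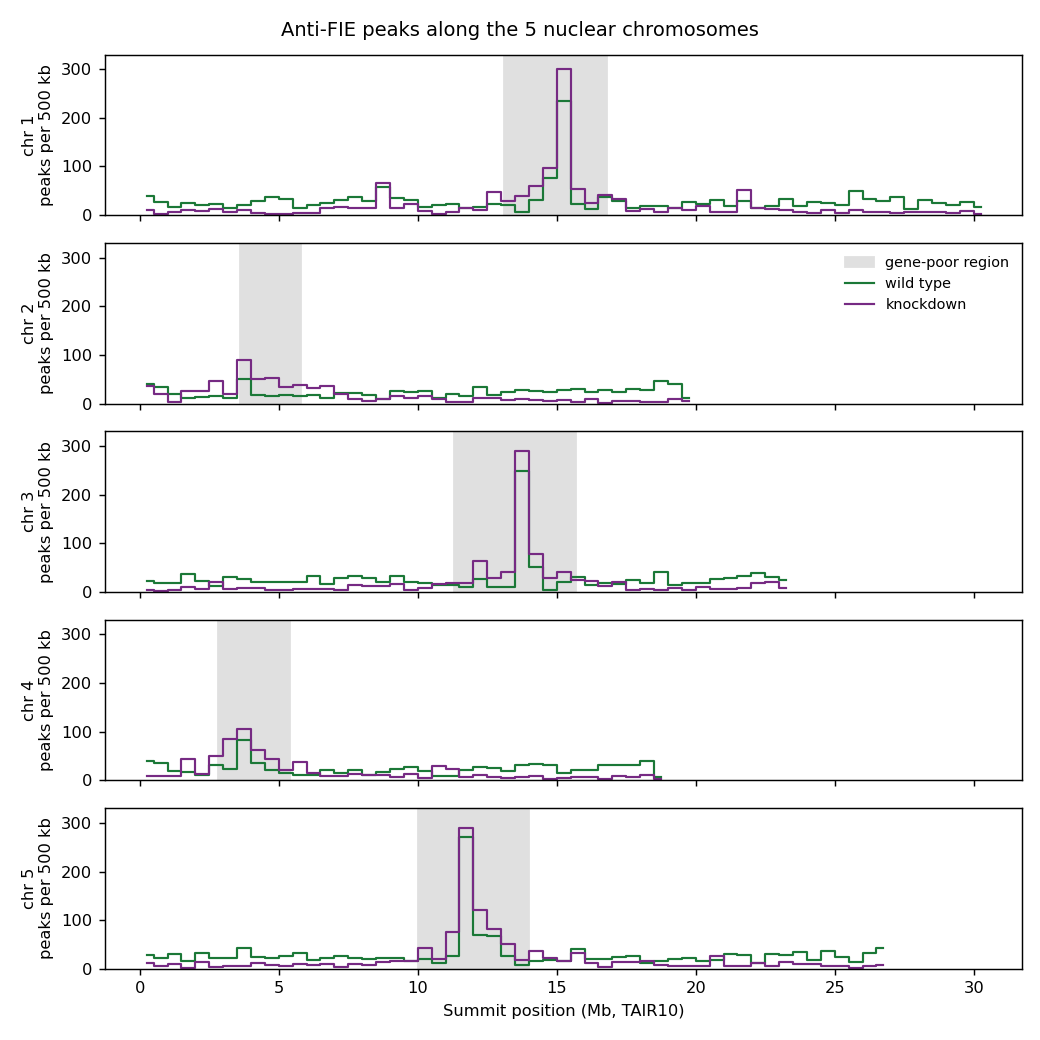
Number of FIE peaks per 500 kb (y axis) along each of the 5 nuclear chromosomes (x axis, Mb, TAIR10) in the wild-type list and the knockdown list, with the gene-poor regions shaded. On the arms the wild-type list had 4900 peaks and the knockdown list 2353, and in the shaded regions they had 1640 and 2529.

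Developmental regulator genes carried FIE in the wild type and in most cases had no FIE peak in the knockdown. Of 125 genes on 12 lists of developmental, chromatin and regulator genes, 76 had a wild-type peak on the gene body and 11 had a knockdown peak. Of the 76, 68 had no knockdown peak. Counting wild-type peaks expected to pass at the knockdown depth, 45 of these genes were bound and 39 had no knockdown peak. For comparison, 2725 of all 27432 protein-coding genes had a wild-type peak (9.93%) and 1206 had a knockdown peak (4.40%). Of the 2725, 2519 had no knockdown peak (92.4%, 91.4 to 93.4). Both lists marked 206 genes, against 119.8 if they were independent (odds ratio 1.94, p = 5.74e-15, two-sided Fisher's exact test). A further 1000 genes had a knockdown peak and no wild-type peak. Counting wild-type peaks expected to pass at the knockdown depth, 742 of all protein-coding genes were bound. Of these, 668 had no knockdown peak (90.0%), so lacking one was common to bound genes at this depth too.

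Genes of floral organ and floral meristem identity were bound most completely, with 14 of 14 bound in the wild type. Their highest folds were at SEP1 (15.8; chromosome 5, 5152382 to 5154501), SEP2 (15.0; chromosome 3, 465782 to 468017) and AG (14.7; chromosome 4, 10383269 to 10387552). These are MADS-box genes that specify floral organs. In the knockdown, 12 of the 14 had no FIE peak. The exceptions were AG, where 4284 bp of wild-type peak faced 408 bp of knockdown peak, and AP1, where 3591 bp faced 144 bp. Leaf polarity genes followed, with 10 of 11 bound in the wild type and 0 in the knockdown. They were led by the YABBY genes FIL (16.98; chromosome 2, 18628039 to 18631195), YAB5 (10.6) and YAB3 (10.1), and by KAN1 (8.13). AS1 had no peak in either list. Expected to pass at the knockdown depth were 13 floral genes, 11 of them without a knockdown peak, and 9 leaf polarity genes. In Fisher's exact tests against all other protein-coding genes, adjusted over the 14 lists by the Benjamini-Hochberg method, p was 1.24e-13 for the floral list and 6.46e-09 for the leaf polarity list.

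Meristem genes were also bound in the wild type, with 8 of 10 genes of the shoot meristem and organ boundary (adjusted p = 1.64e-06, Fisher's exact test). Among them were the boundary gene CUC2 (fold 9.63; chromosome 5, 21900736 to 21904597), the homeobox gene STM (8.51; chromosome 1, 23059629 to 23062630), the stem cell regulator WUS (8.34; chromosome 2, 7808883 to 7811627) and KNAT1 (7.41). In the knockdown, 7 of the 8 had no peak, and CUC3 had one of 112 bp. Expected to pass at the knockdown depth were 6 of them, 5 without a knockdown peak. Of the WOX homeobox genes, 5 of 9 were bound, led by WOX1 (6.25), WOX9 (4.09) and WOX3 (4.02), and none of these 5 had a knockdown peak (adjusted exact p = 0.00134). Of these 5, 3 were expected to pass at the knockdown depth, and WOX9 was not. WOX12 had a peak in the knockdown list alone, of 126 bp. Root and stomatal patterning genes were bound at 6 of 7, with PLT2 of the root stem cell niche at 10.9 and the stomatal genes SPCH and MUTE at 7.40 and 6.35, and at 0 of 7 in the knockdown (adjusted exact p = 1.71e-05). At 3 of the 6, PLT1, SHR and SCR, a loss was not detectable at the knockdown depth.

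Among embryo and seed maturation genes 9 of 16 were bound in the wild type, led by the embryonic regulators FUS3 (fold 9.44; chromosome 3, 9855366 to 9856466), BBM (6.77) and LEC2 (6.15), and none of the 9 had a knockdown peak (adjusted p = 1.71e-05, Fisher's exact test). Of the 9, 4 were expected to pass at the knockdown depth, so a loss was not detectable at the other 5. ABI3 had a knockdown peak of 72 bp and none in the wild type. Flowering time genes were bound at 7 of 14 (adjusted exact p = 3.46e-04), led by the floral repressor SVP at 14.6 (chromosome 2, 9579289 to 9581894), MAF2 at 5.25 and AGL24 at 5.24. FLC had a fold of 3.33, and FT had no peak in either list. AGL24 and AGL19 had knockdown peaks, of 99 and 117 bp. Among the 7, 3 were expected to pass at the knockdown depth, 2 of them without a knockdown peak. Genes of auxin synthesis and transport were bound at 6 of 12 and at 0 of 12 in the knockdown (adjusted exact p = 9.10e-04). Their peaks were weak, at 3.77 for the efflux carrier gene PIN2, 3.63 for the biosynthetic gene TAA1 and 3.62 for PIN7. None of the 6 was expected to pass at the knockdown depth, so a loss was not detectable there.

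BPC genes and C2H2 zinc finger genes of the AZF and ZAT groups also carried FIE in the wild type. Of the BPC genes, 3 of 6 were bound in the wild type and 0 in the knockdown (adjusted p = 0.0218, Fisher's exact test), with BPC2 at a fold of 5.46 (chromosome 1, 5042308 to 5042744), BPC1 at 3.29 and BPC7 at 3.08. BPC2 was the 1 member expected to pass at the knockdown depth, so a loss was not detectable at the others. The over-representation of the BPC list held with the summit in the gene body and was lost under the other 5 alternatives run, with adjusted exact p from 0.0554 to 0.24. Of the AZF and ZAT zinc finger genes, 6 of 10 were bound in the wild type (adjusted exact p = 3.29e-04). Their highest folds were 3.43 at ZAT6 and 3.28 at AZF1. These were also the 2 members with a knockdown peak. ZAT6 was the 1 member expected to pass at the knockdown depth, so a loss was not detectable at the 4 members without a knockdown peak. Among 12 genes for Polycomb subunits and partners, EMF1 had the highest fold of the whole wild-type list, 34.6, and no knockdown peak. CLF, a histone methyltransferase gene of PRC2, had 644 bp of wild-type peak and 615 bp of knockdown peak. MSI1 had a knockdown peak alone, of 94 bp. With 2 of 12 bound in the wild type this list did not pass (adjusted exact p = 0.43). The lists of imprinted and seed development genes (0 of 4), housekeeping genes (0 of 10) and photosynthesis genes (1 of 9, PSAD1) did not pass either, with adjusted exact p of 1, 0.66 and 0.66.

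In all, 10 of the 14 lists were over-represented among wild-type-bound genes. With wild-type peaks expected to pass at the knockdown depth 7 were, and the auxin (0 of 12 bound, adjusted exact p = 1), BPC (1 of 6, adjusted exact p = 0.24) and AZF and ZAT lists (1 of 10, adjusted exact p = 0.34) did not pass. The AZF and ZAT list was also lost with the upper part of the lists by q (2 of 10, adjusted exact p = 0.13), as was the BPC list (2 of 6, adjusted exact p = 0.0554). In the knockdown 0 of the 14 lists were over- or under-represented, and 0 had an unadjusted p under 0.05 by Fisher's exact test. Lists of this size could not show under-representation there, since 4.40% of all protein-coding genes had a knockdown peak. Of the 125 regulator genes pooled, 8.8% had a knockdown peak, against 4.38% of other genes (p = 0.0256, Fisher's exact test). This pooled test was chosen after the results were seen. Without a knockdown input, signal that needs no antibody could give the same. No list was shown to differ from other bound genes in its loss. A greater loss could not be shown, since 92.4% of all bound genes lacked a knockdown peak and a list had at most 14 bound genes. Compared with other bound genes, 0 lists lacked a knockdown peak more or less often, with 0 at an unadjusted p under 0.05. Within quintiles of wild-type fold 0 passed with 1 at an unadjusted p under 0.05. That one was the AZF and ZAT list, with 4 of 6 genes lacking a knockdown peak against 5.62 expected (permutation p = 0.0499, adjusted p = 0.70).

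**Figure D3:**
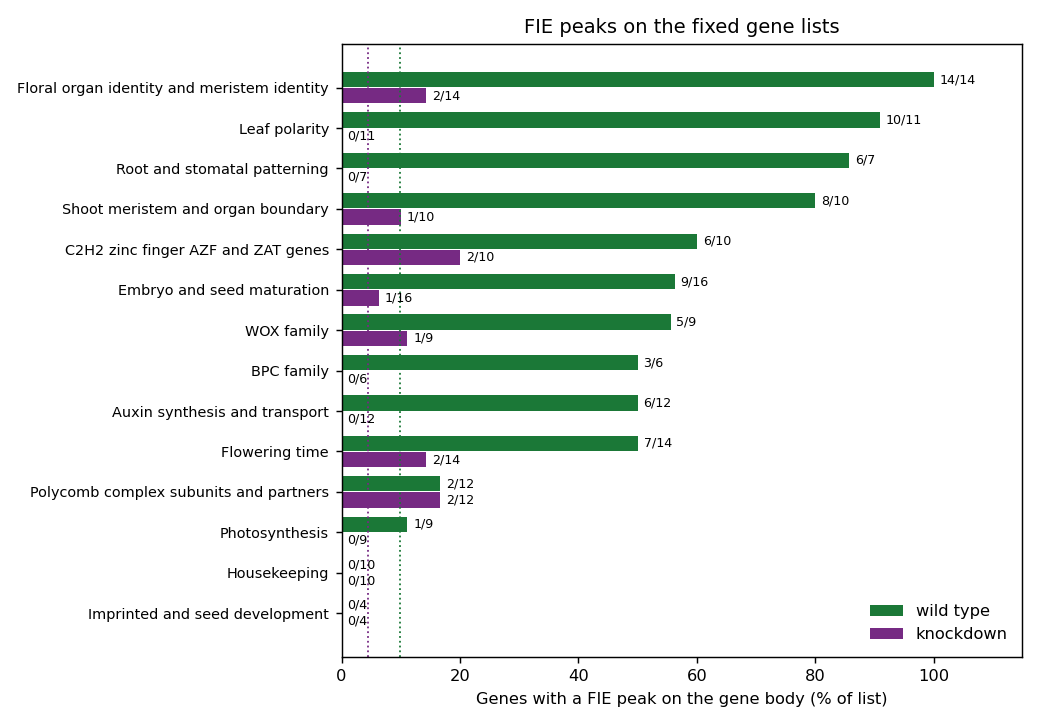
Share of genes with a FIE peak on the gene body (percent of the list, x axis) for the 14 gene lists, in the wild-type list and the knockdown list, with counts beside the bars. Dotted lines mark the shares of all 27432 protein-coding genes, 9.93% in the wild type and 4.40% in the knockdown; the floral list reached 14 of 14 in the wild type and 2 of 14 in the knockdown.

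Most transcription factor families, matched by their gene descriptions, were over-represented among wild-type-bound genes. MADS-box, homeobox and zinc finger genes also stand on the lists above, and other families may share members with them. The families therefore do not count as separate evidence. TCP genes, which control growth and branching, were bound at 14 of 20 in the wild type (70%) and at 0 of 20 in the knockdown (adjusted p = 1.25e-09 for the wild type, Fisher's exact test over 13 families). Homeobox genes were bound at 31 of 67 in the wild type (46.3%, adjusted exact p = 2.96e-13) and 3 of 67 in the knockdown. MADS-box genes were bound at 29 of 98 (29.6%) and at 7 of 98, and NAC genes at 27 of 97 and 2 of 97. At the knockdown depth 8 TCP, 20 homeobox, 19 MADS-box and 15 NAC genes were expected to pass, of which 8, 19, 17 and 14 had no knockdown peak. MYB (37 of 132), WRKY (22 of 72), zinc finger (12 of 36) and bHLH genes (8 of 31) were also over-represented, with adjusted p from 1.57e-08 to 0.0119. Cytochrome P450 genes were bound at 42 of 232 (18.1%, adjusted exact p = 2.33e-04). Ribosomal protein genes were under-represented, with 0 of 67 (adjusted exact p = 0.00231). With wild-type peaks expected to pass at the knockdown depth the calls of the cytochrome P450 and ribosomal protein genes were lost (adjusted exact p = 0.74 and 0.35), as they were with the upper part of the lists by q (adjusted exact p = 0.12 and 0.073). AP2/ERF (5 of 21), histone (5 of 65) and F-box genes (5 of 35) did not pass. In the knockdown 0 of the 13 families passed, with 0 at an unadjusted p under 0.05. Their wild-type-bound genes were not shown to differ in loss from other bound genes, with 0 families past the adjusted test and 0 at an unadjusted p under 0.05 by Fisher's exact test. Families with few bound genes could not show a greater loss, since 92.4% of all bound genes lacked a knockdown peak. Nor could small families show under-representation in the knockdown, where 4.40% of all genes were bound.

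The 10 strongest peaks found only in the wild type lay on the arms, and each would have passed at the knockdown depth. The strongest covered EMF1, which represses flowering with Polycomb (fold 34.6; chromosome 5, 3694619 to 3697939). Next were a peak between STM and AT1G62370 (26.1; chromosome 1, 23065528 to 23066761) and one over AT2G22750 (26.0; chromosome 2, 9671166 to 9674581). STY2, a member of the SHI/STY family, followed (25.3; chromosome 4, 17155544 to 17158378). Peaks between genes lay between AT2G17940 and WUS (22.5; chromosome 2, 7804267 to 7805409) and between the branching gene BRC1 and AT3G18560 (22.5; chromosome 3, 6387413 to 6389786). The other four covered the leaf patterning gene BOP1 with SDP1-LIKE (19.6; chromosome 3, 21147068 to 21150557), AT2G43660 with AT2G43670 (19.4; chromosome 2, 18103789 to 18106703), RR19 (18.2; chromosome 1, 18190719 to 18192181) and STY1 (18.1; chromosome 3, 18961932 to 18966808).

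The strongest shared peaks were of another kind. Of the 5 with the highest wild-type fold, 4 lay in the gene-poor region of chromosome 3, between AT3G32980 and AT3G33187, with folds of 24.3 (13814650 to 13815040), 23.4 (13708317 to 13709216), 22.9 (13705287 to 13708240) and 22.8 (13749844 to 13751772). The fifth covered AT3G06435 and AT3G06436 on the arm of chromosome 3 (21.8; 1969094 to 1971047), where 1954 bp of wild-type peak overlapped a knockdown peak of 84 bp. Peaks found only in the knockdown were short. The 5 strongest were a peak of 145 bp between FANCM and AT1G35537 (fold 13.6; chromosome 1, 13102831 to 13102975), one of 127 bp on the auxin response factor gene ARF23 (12.2; chromosome 1, 16673586 to 16673712), one of 109 bp between AT2G46520 and ARF11 (11.1; chromosome 2, 19100447 to 19100555), one of 202 bp between AT2G12405 and AT2G12461 (10.95; chromosome 2, 5022330 to 5022531) and one of 320 bp on AT2G19360 (10.8; chromosome 2, 8381893 to 8382212).

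Within the wild-type list, shared peaks had a slightly higher fold than peaks found only in the wild type, with medians of 3.53 and 3.25 (difference 0.12 on the log2 scale, two-sided permutation p = 1e-05, the smallest possible). The difference was 0.08 on the arms and 0.18 in the gene-poor regions. Among peaks expected to pass at the knockdown depth the medians were 4.98 and 4.89 and the difference did not pass (0.02 on the log2 scale, permutation p = 0.41). Shared wild-type peaks were shorter over the genome (228 against 260 bp, permutation p = 0.00146). The gap was far wider among peaks expected to pass at the knockdown depth (338 against 846 bp, permutation p = 1e-04, the smallest possible) and in the upper part of both lists by q (271.5 against 466 bp). Of the 681 shared peaks expected to pass, 597 lay in the gene-poor regions. Of the 943 found only in the wild type, 892 lay on the arms. These wider gaps were not tested within regions, so they cannot be told apart from a difference between regions. Over all peaks, the gap did not hold within regions, where the medians were 280 and 279 bp on the arms (permutation p = 0.98) and 217 and 146 bp in the gene-poor regions. Within the knockdown list, shared peaks had a median fold of 5.38 and those found only in the knockdown 4.20 (0.36 on the log2 scale, permutation p = 1e-05). Their median lengths were 274 and 122 bp.

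Wild-type peaks without a knockdown peak lay in protein-coding genes more often than shared ones, with 54.8% of summits against 8.48% for shared peaks (adjusted p = 1.71e-249, Fisher's exact test over 4 classes). On the arms alone the shares were 58.4% and 40.3% (adjusted exact p = 6.73e-08). Genes typed as pseudogenes in the gene table, transcribed ones included, held 2.54% of the arm summits found only in the wild type and 21.0% of those shared. In the gene-poor regions the order was reversed, at 33.2% and 15.8%. Of the knockdown summits on the arms, 49.9% lay in protein-coding genes and 23.5% in pseudogenes. The arms can include sequence next to the gene-poor regions that is also dense in knockdown peaks. On chromosome 2, the run of 500 kb bins dense in knockdown peaks was longer than the gene-poor region of 2.2 Mb. Arm values without such bins were not computed. The share of wild-type peaks without a knockdown peak ranged from 71.5% on chromosome 5 to 86.0% on chromosome 2, and each of the 5 chromosomes differed from the others (largest adjusted p = 0.0291, Fisher's exact test). The difference of chromosome 4 was lost with 50% reciprocal overlap (adjusted exact p = 0.46) and among peaks expected to pass at the knockdown depth (adjusted exact p = 0.11). On the arms alone 2 chromosomes differed, both in the opposite direction to the genome. Chromosome 2 was at 92.1% against 95.5% on the others, and over the genome at 86.0% against 76.3%. Chromosome 3 was at 96.7% against 94.5%, and over the genome at 74.3% against 78.5%.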

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

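The split into arms and gene-poor regions, the depth filter, placement within regions, the stricter gene-poor limit, the 1 kb flanks and the rule of the summit in the gene body were chosen after the data were seen; the other alternatives were planned. Of the values recomputed, 158 kept their direction and side of the threshold or stayed within 1.5 times, 13 counts moved further, 3 values lost their call and 3 reversed. The overlap exceeded random placement under all alternatives run. The shared share of wild-type peaks ranged from 13.2% to 41.9% over the genome, 2.25% to 8.61% on the arms and 45.9% to 92.1% in the gene-poor regions, lowest with 50% reciprocal overlap and highest with the depth filter. The number of gene lists over-represented in the wild type ranged from 7, with the depth filter, to 10, and was 8 with the upper part of both lists by q and 9 with equal list sizes or 1 kb flanks. The length difference of shared and wild-type-only peaks, -32 bp, widened to -508 bp with the depth filter and -194.5 bp with the upper part of both lists by q. These wider differences were not tested within the arms or the gene-poor regions.

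Genes with a wild-type peak and no knockdown peak numbered 1360 with the upper part of both lists by q, 1311 with that of the tested list alone, 668 with the depth filter and 3910 with flanks of 1 kb. Genes in both lists then numbered 74, 123, 74 and 386. Genes with a knockdown peak alone numbered 300 with the upper part of both lists and 1564 with flanks. Regulator genes with a wild-type peak and no knockdown peak numbered 39 with the depth filter. These moves follow from fewer peaks or longer genes. The fold difference of shared and wild-type-only peaks was 0.0244 on the log2 scale with the depth filter (permutation p = 0.4142). The length difference of those peaks turned to 1 bp on the arms (permutation p = 0.98) and 71 bp in the gene-poor regions. The excess of pseudogene summits among shared peaks reversed in the gene-poor regions, to 17.37 points more in wild-type-only peaks. The number of chromosomes that differed was 2 on the arms and 3 in the gene-poor regions. Those on the arms, chromosomes 2 and 3, differed in the opposite direction to the whole genome. For fold, length, pseudogenes and chromosomes the cause was not tested.

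No paired analysis was possible because each group had 1 peak list with no replicate columns, so that no replicate was left out. The planned limit of 5 on −log10 q removed 0 peaks and was replaced by the upper part of each list by q, and counting each summit line moved nothing, since 0 intervals were listed more than once. Motif alternatives and gene rules of 1 kb or more upstream were not run, for want of sequence and strand. The depth of the knockdown list limits statements on 3924 of the 4900 wild-type arm peaks.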

Other observations

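The tests below were chosen after the results were seen. MicroRNA genes had FIE peaks at about the share of protein-coding genes, without regard to gene length. Of 326, 34 had a wild-type peak (10.4%, against 9.93% of protein-coding genes), 13 a knockdown peak (3.99%, against 4.40%) and 6 both. The highest folds were at MIR172a (11.8), MIR165b (10.7), MIR172d (10.7) and MIR160a (9.40), none with a knockdown peak. These belong to families that target AP2-type, HD-ZIP III and auxin response factor transcripts. Next came MIR5015 (9.13) and MIR319a (8.97), also without one. The 3 MIR854 genes bound in the wild type (7.56, 7.23 and 6.72) did have a knockdown peak. Long non-coding RNA genes had a peak at 248 of 3480 in the wild type (7.13%) and 39 in the knockdown (1.12%). Genes typed as pseudogenes went the other way, with 342 of 3917 in the wild type (8.73%) and 813 in the knockdown (20.8%), 213 of them in both. Transposable element genes were not told apart within this class. Transcribed pseudogenes, counted apart here, changed less, with 43 of 926 in the wild type (4.64%) and 56 in the knockdown (6.05%). All 4 ribosomal RNA genes of the table had a peak in both lists. These shares were not tested against each other or adjusted for gene length, and a longer gene overlaps a peak more readily.

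STY1 and STY2 of the SHI/STY family, which regulates auxin synthesis and organ development, lay under 2 of the 10 strongest wild-type-only peaks, and the whole family was therefore looked up. Of the 8 other members, 5 had a wild-type peak (62.5%, against 9.92% of other genes, p = 4.17e-04, Fisher's exact test), namely SRS7 (fold 18.8), SHI (15.6), LRP1 (14.6), SRS5 (3.94) and SRS4 (3.65). Binding across much of the family in the wild type is consistent with this test. Of the 5, 4 had no knockdown peak, and SRS7 had one of 204 bp against 3820 bp in the wild type. Of the 5, 3 were expected to pass at the knockdown depth, 2 of them without a knockdown peak, so a loss was not detectable at the other two.

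Wild-type arm peaks without a knockdown peak may reflect loss of FIE in the double knockdown, a lower depth, or a weaker precipitation. Lower depth is argued against for the peaks strong enough to pass, 91.4% of which had no knockdown peak (95% interval 89.5 to 93.0), and it cannot be told apart from loss for most of the 3760 weak ones: 164 of the 3924 weak arm peaks were shared where thinning expected 320.1 (SD 15.3), but the same expectation was far from the 618 shared among weak gene-poor peaks (104.7). A mild common loss of enrichment would keep the strongest peaks, but 9.39% of the 490 strongest arm peaks were shared. Sharing did rise with wild-type fold, from 2.25% to 5.10% in the weaker groups of 490 to 8.98% in the group below the strongest. The chance that a shared arm peak had the higher wild-type fold was 0.60 (95% bootstrap interval 0.56 to 0.64). This value cannot decide on a large common loss. Random placement alone gave 1.45% shared on the arms, so part of the shared peaks need not be kept signal. Near-complete failure of the knockdown precipitation stays open. Knockdown peaks fell on 8.8% of regulator genes and 4.38% of other genes (p = 0.0256, Fisher's exact test), but signal that needs no antibody could give the same. The 9 libraries held no knockdown input and no mock precipitation. A biological effect of the knockdown was not tested apart from these, since it is confounded with the library group.

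Peaks shared in the gene-poor regions could come from sequence copies that the reference lacks, which raise both precipitate and input. Of the 1215 shared peaks, 476 had a control at the lowest genome background and a median fold of 4.26. If that control was the input, this argues against extra copies seen in the input for these 476. How the input entered the lists is not given. For the other 739 the control was above that background, with a median fold of 3.20, and extra copies cannot be told apart from binding, since the control of the caller may average over wider windows. No biological explanation was tested for them, as the design names none.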
